A study of Mus musculus with 39 samples.

How the data were processed

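Messenger RNA was measured in 39 libraries of E14 mouse embryonic stem cells, a line derived from the blastocyst. The cells were wild type (WT) or carried a knockout (KO) of Esrrb, which encodes the orphan nuclear receptor oestrogen-related receptor beta. The KO cells came as 3 lines, named KO1, KO2 and KO3 in the labels. Per the labels' protocols, cells grew on gelatin in serum-free N2B27 medium with 2iL. The term 2iL stands for CHIR99021, an inhibitor of glycogen synthase kinase, PD0325901, an inhibitor of the kinase MEK, and the cytokine LIF, which together hold the cells in naive pluripotency. Withdrawal means that the cells were moved to N2B27 medium without 2iL and collected after 24, 48 or 72 h. Libraries were made with a digital mRNA kit, which counts reads near the 3' end of transcripts.

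The authors deposited a table of read counts per Ensembl gene for each library. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.6.0a and HTSeq with genome build mm10. The annotation release, read trimming, collapsing of molecular identifiers and strand setting are not given in the sources used here. Values of overlapping or antisense genes are thus uncertain. Most named ones are marked, but not Pth1r, Smarcd3, Msc, Esrp1, S100a4, Pou5f1, Eomes or Gata6. Each count table lists 31053 genes, of which 30934 were matched by identifier to a symbol of the reference annotation, a mouse annotation of the same build. A total of 28 symbols belong to 2 or more identifiers. Rows that name no gene were kept out of library sizes and tests. Over the libraries, 59.8 to 67.6% of the reads in a table lay in genes, 5.99 to 17.4% had no feature, 0.33 to 0.722% were ambiguous and 19.2 to 27.6% were not uniquely aligned. The authors also deposited 1 table for the whole series whose name calls its values CPM (counts per 1000000 counts). Its values were not used, and they were treated as a score of unknown scale, since as deposited by the authors they are not CPM. Each of its 506726 values above 0 equalled, within a relative tolerance of 1e-06, the deposited count divided by the total of another library in a rotating order, and 2.546% matched the library's own total. The column sums of that table ran from 104215.6 to 6715179, and its values lay a median 1.591-fold from the true CPM, with 33.88% off by more than 2-fold. All CPM printed here were therefore computed from the counts.

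The libraries held between 139071 and 10033233 counts in genes, with a median of 2706517, and 3 libraries lay under 1000000. File names carry 3 run dates, which hold 30, 5 and 4 libraries. The main fits had no term for the date. Intervals on single counts and shares are exact 95% intervals (Clopper-Pearson for shares) and cover counting error only, since reads are not independent molecules. Where a group had 0 counts of a gene, the fold was computed against a floor of 3 counts over the group. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries of a group agreed within sampling noise, and each library was counted once.

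Tests were run with edgeR 4.0.16 in R 4.3.3, with TMM (trimmed mean of M values) normalisation and the quasi-likelihood F test. The filter filterByExpr left 13187 genes and removed 17866. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested in a comparison. KO was compared with WT in each condition in a fit with 8 groups of genotype and condition, in which the spread includes the spread between KO lines (biological coefficient of variation 0.519). Responses to withdrawal, their difference between genotypes and the differences among the KO lines came from a fit with 16 groups of line and condition (coefficient 0.463), in which the KO response is the equal-weight mean of the 3 lines. Each fit used all 39 libraries for 1 estimate of the spread. The same fit gave the contrast of each line against the mean of the other 3.

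The direction of 29 gene lists, written before the data were examined, was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists in each of the 13 contrasts. The test was repeated with the correlation estimated from the data, and the adjusted p of that test is given where it ends a call. The lists covered states of pluripotency, early lineages, signalling targets, metabolism, stress, imprinted genes and other cell types. Counts "adjusted over the list alone" use the members of a list as the only genes tested. Genes named in the text followed a rule fixed at the same time. It took Esrrb, a panel of 16 further genes whatever their result, and for KO against WT the 8 largest changes in each direction among called genes with the same sign in all 3 lines and at least 10 CPM in the higher group. For withdrawal responses and their differences it took the 5 largest in each direction. For each list it took up to 4 members with the smallest p and members that moved against the list. Genes without an established name were passed over, and 2 genes that the rule took are not reported here, though counts over the named genes include them. Gm42418 and the genes named for the differences among the KO lines and for other tissues in the later run dates lie outside the rule and were chosen after their values were seen.

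The alternatives fixed in advance were DESeq2 1.42.0 with its own size factors, those factors inside edgeR, no expression filter, the replicate number as a block, the run date as a term, libraries of at least 1000000 counts, the earliest run date alone, line as the unit, each KO line left out, equal weights for the lines, a test against a 2-fold change, and each library left out in turn. Leaving out libraries in which gene Gm42418 took at least 20% of the counts, leaving out chromosomes 6, 8 and 14, libraries numbered 1 and 2 without a number term, and the earliest run for the withdrawal responses, their differences between genotypes, the differences among the KO lines and the gene lists were added after seeing the data. Another scaling by DESeq2 factors shifted the median difference between KO and WT by 0.015 to 0.087 on the log2 scale.

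The fits were tested on simulated counts with the depths and spread of these libraries, each drawn independently, so similarity within a line is not covered. For KO against WT in 2iL, edgeR recovered 6, 41.8 and 69.7% of genes changed 2-, 4- and 8-fold. Of its calls 3.6 to 6.4% in the 4 conditions were unchanged genes. A shift of 0.585 (log2) put into a chromosome was recovered as 0.542 over 5724 genes, with others within 0.057.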

Results

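The data were 3' mRNA counts from wild-type (WT) and Esrrb knockout (KO) E14 mouse embryonic stem cells kept in 2iL or collected 24, 48 or 72 h after its withdrawal. WT had 2 libraries in each of the 4 conditions. Line KO1 had 3 libraries in 2iL and 2 at each later time, KO2 had 4 at 48 h and 2 in the other conditions, and KO3 had 4 at 24 h, 4 at 48 h and 2 in the others. KO and WT were therefore compared with 7 against 2 libraries in 2iL, 8 against 2 at 24 h, 10 against 2 at 48 h and 6 against 2 at 72 h. Total counts in genes ran from 139071 in KO2 at 48 h, replicate 1, to 10033233 in KO1 at 48 h, replicate 2. The other libraries under 1000000 counts were KO2 at 48 h, replicate 2 (433994) and KO3 at 48 h, replicate 1 (517611). Gene Gm42418, which overlaps a ribosomal RNA repeat, took from 2.28% (exact 95% interval 2.26 to 2.31) of the counts in KO1 in 2iL, replicate 3, to 23.9% (23.9 to 24.0) in KO3 at 48 h, replicate 4. The first principal component held 23.1% of the variance of 1000 variable genes. Its mean fell by time in each line, in WT from 39.3 in 2iL to -8.8 at 72 h and in KO1 from 5.3 to -45.3.

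Genes of connective tissue moved with the run date. S100a4, a calcium-binding protein of fibroblasts and other mesenchymal cells, lay between 55.9 and 326 CPM in the 9 libraries of the 2 later run dates and at most at 8.73 CPM in the 30 libraries of the first. Col1a2, a chain of type I collagen, reached at least 41.9 CPM in the later libraries and at most 16.1 in the first. Later libraries made up 2 of 3 in KO1 in 2iL, 2 of 4 in KO3 at 24 h, 2 of 4 in KO2 and in KO3 at 48 h, and 1 of 2 in WT at 48 h. No other group held any. Within groups the Wnt target Sp5 was lower in the later libraries (-4.10, adjusted p = 1.3e-05), and Krt19, Tpi1, Cald1, Serpinh1, Slc4a8, Pou3f1, Dnmt3a, Nanog, Sox2, Bcl11a, Esrrb and Peg10 also differed (0.0049 to 0.036).

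Esrrb, on chromosome 12 from 86361117 to 86521628 (mm10), encodes a nuclear receptor that is part of the naive pluripotency network. In WT it lay at 275 ± 8.29 CPM in 2iL, 134 ± 15.8 at 24 h, 81.2 ± 13.2 at 48 h and 28.3 ± 8.39 at 72 h (SD, n = 2 each). KO1 held 245 ± 55.4 CPM in 2iL (n = 3) and then 18.4 ± 1.92, 5.28 ± 1.06 and 2.6 ± 1.62 (n = 2 each). KO2 held 35.1 ± 1.99 CPM in 2iL (n = 2), 29.7 ± 16.2 at 24 h (n = 2), 29.3 ± 31.5 at 48 h (n = 4, or 14.2 ± 11.1 without replicate 1) and 6.96 ± 2.17 at 72 h (n = 2). KO3 held 133 ± 33.2 CPM in 2iL (n = 2), 65.7 ± 54.7 at 24 h (n = 4, or 38.8 ± 12 without replicate 2), 22.0 ± 6.35 at 48 h (n = 4) and 9.34 ± 2.95 at 72 h (n = 2). Each of the 39 libraries had Esrrb counts. The log2 difference of KO from WT was -0.85 (SE 0.62), -1.61 (0.59), -2.32 (0.59) and -2.15 (0.68) in the 4 conditions, and none passed the edgeR test (adjusted p = 0.81, 0.47, 0.087 and 0.19), although those at 24, 48 and 72 h passed in 2, 4 and 2 of 15 other settings. The kit reads the 3' end of transcripts and the position of the deletion is not given in the sources used here, so a tag outside the deleted part checks nothing and these counts neither bear out nor contradict the labels.

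**Figure D1:**
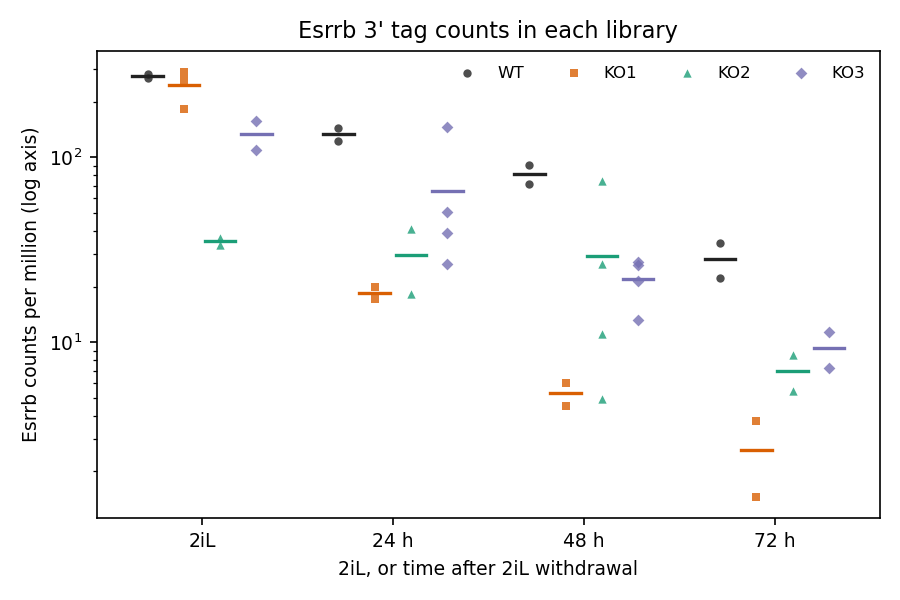
Esrrb CPM (log axis) in each of the 39 libraries, by line and condition; bars mark the mean of each line and condition. KO1 lies at 245 CPM in 2iL, near WT at 275 CPM, and at 2.6 CPM at 72 h.

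Genes of chromosomes 6 and 8 lay higher or lower as a whole in KO lines, and those of chromosome 14 in segments. Over 5718 genes with a mean of at least 20 CPM, the median gene of chromosome 8 differed from WT by -0.52 (log2) in KO1. It differed by -0.42 in KO2 and 0.01 in KO3 (9, 10 and 12 against 8 libraries). Each pair is 1 line against 1, on chromosomes chosen after their shifts were seen, so no p is given. On chromosome 6 the median gene was higher than in WT by 0.49 in KO1, 0.34 in KO2 and 0.31 in KO3. On chromosome 14 the shift lay in segments, with 1.02 in KO1 at 40 to 50 Mb and 0.81 in KO3 at 70 to 80 Mb. The line means of the other 17 chromosomes lay within 0.068 of 0. Genes of these 3 chromosomes made up 13.6% of the genes tested, 14.5% of those called between KO and WT in 2iL and 35.2% of those called among the KO lines at 24 h.

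**Figure D2:**
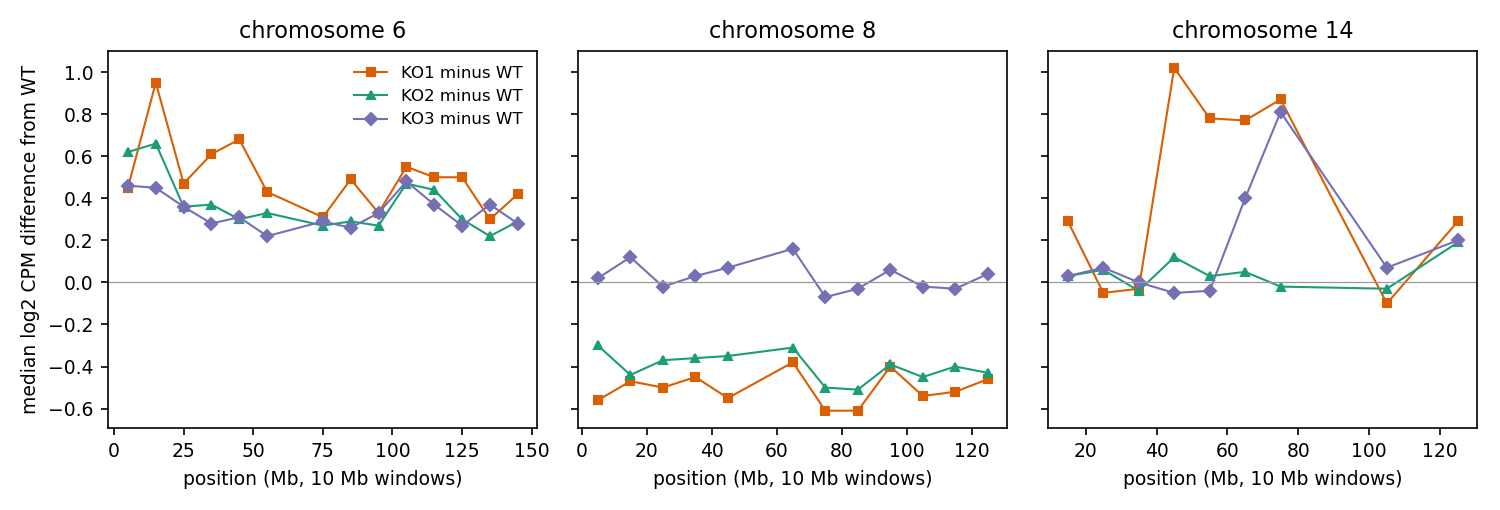
Median log2 CPM difference of each KO line from WT in windows of 10 Mb along chromosomes 6, 8 and 14. KO1 and KO2 lie below 0 along chromosome 8, where KO3 lies near 0, and the 3 KO lines lie above 0 along chromosome 6.

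In 2iL, genes of the trophectoderm, the first extra-embryonic lineage, were higher in KO than in WT cells. Rhox6, a homeobox gene of placenta and germ cells on chromosome X (37826910 to 37829857), lay at 32.5 ± 9.71 CPM in KO (SD, n = 7) against 1.99 ± 0.283 in WT (n = 2), a log2 difference of 4.00 (SE 0.70, adjusted p = 0.00078). Its neighbour Rhox9 rose by 3.78 (adjusted p = 0.0047), although the 2 genes are close relatives between which reads can be split. Krt18, a keratin of simple epithelia, rose by 2.74 (adjusted p = 0.0043). Of the 19 trophectoderm genes tested, 3 rose and none fell over all genes, and 9 rose when adjusted over the list alone. The list as a whole was higher (camera adjusted p = 2.33e-08, and 0.0357 with an estimated correlation).

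Imprinted genes, which are read from 1 parental copy, were also higher in 2iL. H19, a non-coding RNA of fetal and placental tissue on chromosome 7 (142575529 to 142578143), lay at 441 ± 274 CPM in KO and 12.7 ± 2.73 in WT, a log2 difference of 5.12 (SE 0.94, adjusted p = 0.0013). Peg10, on chromosome 6, which the placenta needs, rose by 4.16 (adjusted p = 0.024), Peg3 by 2.24 (0.014) and Cdkn1c, an inhibitor of cyclin-dependent kinases that overlaps another counted gene, by 2.52 (0.027). Of the 20 imprinted genes tested, 5 rose and none fell over all genes, while 7 rose and 1 fell when adjusted over the list alone. The list passed the test (adjusted p = 2.33e-08, and 0.000494 with an estimated correlation). Plagl1, an imprinted zinc finger gene, went against the list at -2.70 (adjusted p = 0.05). Among 17 p53 targets 2 rose over all genes and 3 adjusted over the list alone (list adjusted p = 3.49e-05, and 0.000576 with an estimated correlation). They included Pmaip1, a BH3-only gene of cell death, which rose by 3.03 (adjusted p = 0.0013), and Perp, a membrane protein of desmosomes, which rose by 2.50 (0.047).

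Naive pluripotency genes were lower in KO cells in 2iL. Klf4, a transcription factor downstream of LIF, lay at 56.3 ± 21.0 CPM in KO and 225 ± 17.8 in WT, a log2 difference of -1.99 (SE 0.52, adjusted p = 0.042). Tfcp2l1 fell by 1.73 (adjusted p = 0.043), Tcl1, a cofactor of the kinase Akt, fell by 2.22 (0.012) and Fgf4 fell by 1.74 (0.047). Of the 20 members 4 fell and none rose over all genes, and 6 fell when adjusted over the list alone (list adjusted p = 1.04e-05, but adjusted p = 0.12 with an estimated correlation). Of 21 genes of the formative state, which follows the naive one, Dnmt3a, a de novo DNA methyltransferase that overlaps an antisense gene, rose by 1.66 (adjusted p = 0.017). Otx2, a homeobox gene of chromosome 14 that also overlaps an antisense gene, fell by 1.46 (0.02). Adjusted over the list alone, 6 formative genes rose and 2 fell, and the list was higher (adjusted p = 0.00126, but adjusted p = 0.134 with an estimated correlation). The fibroblast list was higher as well (adjusted p = 0.00727, but adjusted p = 0.421 with an estimated correlation), with none of 13 members past the test, and that call ended in the libraries of the earliest run date.

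In 2iL Lamb1, a laminin chain of the basement membrane, also rose, by 2.23 (adjusted p = 0.0016), Esrp1, a splicing factor of epithelia, by 2.67 (0.012) and Serpinh1, a collagen chaperone, by 2.28 (0.019), to 197 ± 89.2 CPM in KO from 40.5 ± 8.02 in WT. Of 20 epithelial genes 2 rose over all genes, while 5 rose and 1 fell adjusted over the list alone (list adjusted p = 0.00517, but adjusted p = 0.134 with an estimated correlation). Of 17 primitive endoderm genes 2 rose over all genes and 4 adjusted over the list alone (0.00727, but 0.134 with an estimated correlation). LIF/STAT3 targets, which share 5 genes with the naive list, were lower, 2 of 14 by either count (0.00749, but 0.134 with an estimated correlation). Genes of the integrated stress response were lower (0.00282, but 0.106 with an estimated correlation). So were nuclear genes of oxidative phosphorylation (3.1e-07, but 0.134 with an estimated correlation). Of these 51 genes none passed over all genes and 3 did adjusted over the list alone.

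The largest falls in 2iL lay outside the lists. Ak4, an adenylate kinase of mitochondria on chromosome 4 (101419277 to 101466995), lay at 4.28 ± 1.35 CPM in KO and 224 ± 41.9 in WT, a log2 difference of -5.67 (SE 0.55, adjusted p = 1e-09). Ly6a, the surface antigen Sca-1, fell by 5.61 (adjusted p = 2.6e-07). Cobl, a nucleator of actin filaments that overlaps a predicted gene, fell by 4.40 (2.6e-07), with 5.47 ± 4.16 CPM in KO and 121 ± 0.451 in WT. Also lower were St8sia1, a sialyltransferase gene of chromosome 6, at -4.50 (0.011), the muscle transcription factor gene Msc at -5.25 (0.0043), Klk1 at -5.43 (0.012), Smarcd3, a subunit of chromatin remodelling complexes, at -4.32 (0.0099), and Grin1, a glutamate receptor gene that overlaps an antisense gene, at -4.60 (0.017). Also higher were Pth1r, the receptor of parathyroid hormone, at 3.67 (0.018), Emp3 at 3.60 (0.015) and Parp10, which overlaps Plec, at 4.60 (0.027). Nrk, a kinase gene of the placenta, had 331 counts in KO and 3 in WT, a ratio of 40.5 (exact 95% counting interval 13.7 to 197).

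Over all genes in 2iL, 124 were called, 57 higher and 67 lower in KO, of 13187 tested. All 124 had the same sign in the 3 KO lines, against 53.1% of all genes. In counts simulated with no difference against the same WT libraries, 51.2% of all genes and 100% of the 124 with the smallest p had the same sign. Klf4 and Tfcp2l1 kept their calls in 9 of 15 other settings and in 2 of 9 fits without 1 library. The count fell to 6 without WT replicate 1 and to 10 without WT replicate 2, and to 20 with line as the unit. DESeq2 called 237, 167 higher and 70 lower, and leaving out KO3 gave 220.

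**Figure D3:**
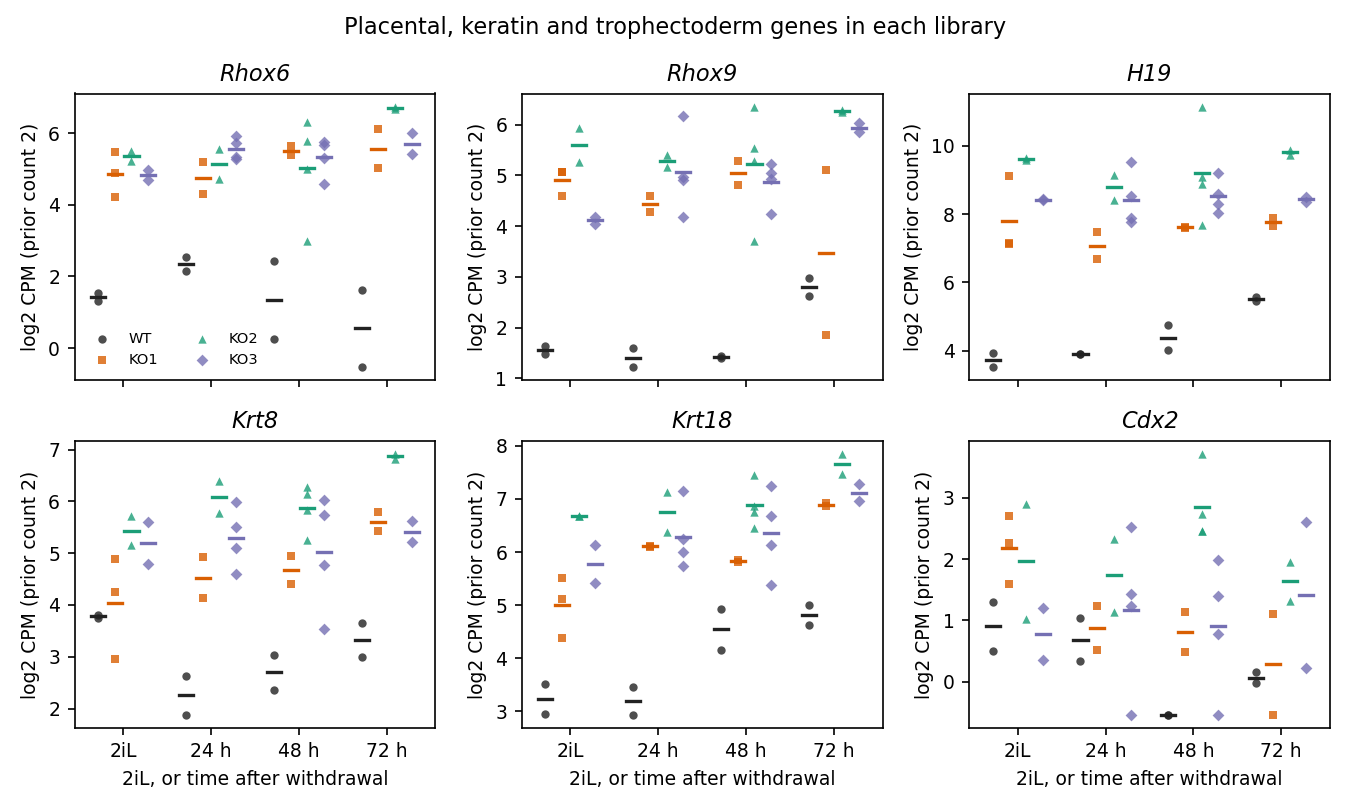
Log2 CPM (prior count 2) of trophectoderm genes and the imprinted gene H19 in each library, by line and condition. Bars mark the mean log2 CPM of each line and condition. The mean CPM of Rhox6 over all KO libraries is 32.5 against 1.99 in WT in 2iL, and 69.1 against 1.21 at 72 h.

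At 24 h after withdrawal, trophectoderm genes again stood above WT. Krt18 lay at 86.3 ± 34.5 CPM in KO (SD, n = 8) against 8.64 ± 2.39 in WT (n = 2), a log2 difference of 3.32 (SE 0.56, adjusted p = 0.0024). Its partner keratin gene Krt8, which overlaps a predicted gene, rose by 3.35 (adjusted p = 0.02). Rhox6 rose by 3.12 (adjusted p = 0.014) and Rhox9 by 4.05 (0.0093). Sct, which encodes the hormone secretin, had 246 counts in KO and 2 in WT, a ratio of 42.9 (exact 95% counting interval 11.7 to 356, adjusted p = 0.022). Of 19 trophectoderm genes 5 rose and none fell over all genes, and 8 rose when adjusted over the list alone (list adjusted p = 1.52e-11, and 0.00794 with an estimated correlation).

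H19 rose by 4.58 at 24 h (SE 0.91, adjusted p = 0.013), from 14.3 ± 0.149 CPM in WT to 343 ± 214 in KO. It was the 1 imprinted gene of 20 past the test over all genes, with 3 adjusted over the list alone (list adjusted p = 2.01e-07, and 0.000695 with an estimated correlation). None of 17 p53 targets passed over all genes and 6 rose adjusted over the list alone (list adjusted p = 2.01e-07, and 3.99e-05 with an estimated correlation). Pmaip1 differed by 1.86 (adjusted p = 0.085) and Perp by 2.44 (0.13). Lamb1 rose by 2.21 (SE 0.42, adjusted p = 0.0089), to 55.3 ± 15.8 CPM from 12 ± 2.72. It is a member of 2 lists. Of 20 epithelial and polarity genes it alone passed over all genes and 5 rose adjusted over the list alone (list adjusted p = 3.01e-07, and 0.0111 with an estimated correlation). Of 17 primitive endoderm genes it alone passed by either count, and that list was higher (adjusted p = 0.00111, but adjusted p = 0.055 with an estimated correlation), a call that ended without KO3.

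None of 20 naive pluripotency genes passed over all genes at 24 h, while 6 were lower when adjusted over the list alone (list adjusted p = 3.01e-07, but adjusted p = 0.055 with an estimated correlation). Tfcp2l1, a transcription factor of the naive network, lay at 33.4 ± 12.9 CPM in KO and 117 ± 11.6 in WT (-1.82, adjusted p = 0.075), and passed in 5 of 15 other settings. LIF/STAT3 targets were lower as a list (adjusted p = 0.00303, but adjusted p = 0.0763 with an estimated correlation) and genes of cholesterol synthesis higher (2.38e-06, but adjusted p = 0.055 with an estimated correlation), each with no member past the test over all genes. Adjusted over the list alone, 3 of 14 and 2 of 23 passed. The formative list was higher (adjusted p = 0.023, but adjusted p = 0.384 with an estimated correlation), with 1 of 21 adjusted over the list alone. The fibroblast list moved with the run date here as well, and its call (adjusted p = 0.0108, but adjusted p = 0.425 with an estimated correlation) ended in the libraries of the earliest run.

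Outside the lists at 24 h, Cobl fell by 4.35 (SE 0.52, adjusted p = 5.5e-07), to 5.27 ± 2.92 CPM from 107 ± 6.47. St8sia1, on chromosome 6, fell by 4.68 (adjusted p = 0.021), Aard by 4.67 (0.023), the channel gene Pkd2l1 fell by 3.96 (0.036), Ly6a by 3.10 (0.027) and Jam2, a junctional adhesion molecule, by 2.89 (0.032). Also lower were Khdc3, a component of the maternal complex of early embryos that overlaps a predicted gene, at -3.06 (0.014), and Dgkeos at -5.53 (0.025), an antisense gene whose reads cannot be told from those of Dgke. Igdcc4 rose by 2.89 (0.022). In all, 24 genes were called, 10 higher and 14 lower, and 8 of them also passed in each KO line alone. They shared their sign in the 3 lines, against 49.1% of all genes, where simulation with no difference gave 52.7% of all genes and 100% of the 24 with the smallest p. Of 10 fits without 1 library, Dgkeos and Pkd2l1 kept their calls in 3 and Ly6a and Jam2 in 4. Krt8, Krt18, Rhox6, Rhox9 and H19 kept theirs in 8 of 10. Every call of a gene higher in KO at 24 h needed both WT libraries. The count fell to 1 without WT replicate 1 and to 1 without WT replicate 2, and to 1 with line as the unit. DESeq2 called 85 higher and 16 lower, the earliest run alone gave 60, and leaving out KO3 gave 82.

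At 48 h, Rhox6 lay at 42.7 ± 19.5 CPM in KO (SD, n = 10) and 2.61 ± 2.98 in WT (n = 2), a log2 difference of 3.91 (SE 0.68, adjusted p = 0.0024), and Rhox9 rose by 4.20 (0.0066). These were the 2 of 19 trophectoderm genes past the test over all genes, with 8 adjusted over the list alone (list adjusted p = 6.28e-13, and 0.00656 with an estimated correlation). H19 rose by 4.69 (SE 0.91, adjusted p = 0.0071), at 543 ± 623 CPM in KO and 20.9 ± 7.43 in WT. Without KO2 replicate 4, at 2268 CPM, the KO mean was 351 CPM and the log2 difference 4.07 (adjusted p = 0.0023). Of 20 imprinted genes it alone passed over all genes and 8 rose adjusted over the list alone (list adjusted p = 1.54e-10, and 7.78e-05 with an estimated correlation). Lamb1 rose by 2.37 (SE 0.42, adjusted p = 0.0024), from 16.6 ± 0.0434 CPM to 87.2 ± 23.1, as the 1 member of 17 in the primitive endoderm list by either count (list adjusted p = 1.11e-05, and 0.0151 with an estimated correlation).

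Cldn6, a claudin of tight junctions in early epithelia, had 414 counts in KO at 48 h and 0 in WT, at least 28.8-fold higher against a floor of 3 counts over the group. With Lamb1 it made up the 2 of 20 epithelial genes past the test by either count (list adjusted p = 0.0034, but adjusted p = 0.141 with an estimated correlation). Nrk had 627 counts in KO and 2 in WT, a ratio of 65.5 (exact 95% counting interval 18.0 to 542). Irx3, a homeobox gene of chromosome 8 that overlaps an antisense gene, rose by 3.74 (SE 0.75, adjusted p = 0.0096), and Pttg1, the securin of chromosome separation, by 1.56 (0.041). Of the 17 p53 targets none passed over all genes, while 6 were higher and 1 lower when adjusted over the list alone (list adjusted p = 0.00613, and 0.0151 with an estimated correlation), and that call ended in libraries of at least 1000000 counts and with line as the unit.

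Naive genes at 48 h had 10 of 20 members lower when adjusted over the list alone and none over all genes (list adjusted p = 1.01e-06, but adjusted p = 0.0784 with an estimated correlation). Zfp42, the naive marker Rex1 on chromosome 8, lay at 44.3 ± 26.8 CPM in KO and 129 ± 103 in WT (-1.64, adjusted p = 0.23). Shared pluripotency genes were lower as a list, 4 of 12 adjusted over the list alone (adjusted p = 0.00261, but adjusted p = 0.11 with an estimated correlation). Rpp25, a subunit of ribonuclease P, fell by 2.16 (SE 0.39, adjusted p = 0.0031) from 182 ± 40.5 CPM in WT to 42.1 ± 14.4. Mybl2, a transcription factor of the cell cycle, fell by 1.89 (0.01), Upp1, which breaks down uridine, by 1.87 (0.041), Ech1, an enzyme of fatty acid oxidation, by 1.90 (0.008), Twf2, an actin-binding protein, by 1.83 (0.013) and the corepressor gene Aes by 2.06 (0.042). The call of Upp1 ended in all but 5 of 15 other settings and 2 of 12 fits without 1 library, and that of Aes in all but 9 and 4. Pfkp, a phosphofructokinase gene that overlaps Pitrm1, fell by 2.08 (0.0096) and Csad, which makes hypotaurine and overlaps Zfp740, by 1.82 (0.0098).

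Over all genes at 48 h, 26 were called, 8 higher and 18 lower, and 11 of them also passed in each line alone. With DESeq2 size factors inside edgeR the 24 calls split into 11 higher and 13 lower. All 26 shared their sign in the 3 lines, against 57.0% of all genes, where simulation with no difference gave 54.2% and 100% of the 26 with the smallest p. The count fell to 3 without WT replicate 1, to 1 without WT replicate 2, to 2 in the earliest run and to 2 with line as the unit. DESeq2 called 87, 68 higher and 19 lower, and leaving out KO1, KO2 or KO3 gave 46, 14 and 112.

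At 72 h, Rhox6 lay at 69.1 ± 30.4 CPM in KO (SD, n = 6) and 1.21 ± 1.71 in WT (n = 2), a log2 difference of 5.65 (SE 0.78, adjusted p = 4.1e-05). Sct rose by 4.66 (SE 0.95, adjusted p = 0.015), to 55.0 ± 31.3 CPM from 2.02 ± 2.26, and Krt19, a keratin of simple epithelia, by 4.60 (SE 1.01, 0.028). Krt18 rose by 2.46 (0.026). These 4 were the trophectoderm genes of 19 past the test over all genes, and 8 rose adjusted over the list alone (list adjusted p = 1.21e-12, and 0.0148 with an estimated correlation). Primitive endoderm genes were higher as a list (adjusted p = 6.72e-05, and 0.0273 with an estimated correlation), with none of 17 past the test over all genes and 5 adjusted over the list alone. Mesendoderm genes were higher too (adjusted p = 0.0114, and 0.0362 with an estimated correlation), with none of 17 past the test by either count, and that call ended without KO2.

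Naive genes were lower at 72 h. Zfp42, on chromosome 8, fell by 3.00 (SE 0.61, adjusted p = 0.015) from 87.4 ± 27.5 CPM in WT to 11 ± 5.68 in KO, and Nr0b1, a nuclear receptor of the same network, by 3.54 (SE 0.82, 0.041) from 11.8 ± 3.02 to 0.952 ± 0.512. These were the 2 of 20 past the test over all genes, while 6 were lower and 1 higher when adjusted over the list alone (list adjusted p = 6.72e-05, but adjusted p = 0.102 with an estimated correlation). Foxd3, a forkhead gene of the transition out of the naive state, fell by 2.22 (SE 0.45, adjusted p = 0.015), and Tdrd12, of the piRNA pathway, by 1.94 (0.026). The shared pluripotency list was lower (adjusted p = 0.000192, but adjusted p = 0.0522 with an estimated correlation), as was the proliferation list (0.000814, but adjusted p = 0.0733 with an estimated correlation). The DNA methylation machinery was lower (adjusted p = 0.00562, and 0.0273 with an estimated correlation), with none of 12 members past the test by either count, and that call ended without the libraries of at least 20% Gm42418. Neuroectoderm genes were higher (adjusted p = 0.000233, but adjusted p = 0.0671 with an estimated correlation), 2 of 16 adjusted over the list alone.

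Among other genes at 72 h, Adck2, on chromosome 6 and overlapped by predicted genes, had 198 counts in KO and 0 in WT, at least 28.0-fold higher. Amot, a regulator of Hippo signalling, rose by 3.36 (SE 0.77, adjusted p = 0.041), Csrp1, a LIM protein of actin fibres, by 2.24 (0.026), and Cald1, the actin-binding caldesmon on chromosome 6 that overlaps other genes, by 2.08 (0.037). Triml2, on chromosome 8, fell by 2.86 (SE 0.53, adjusted p = 0.0073), the zinc finger gene Zfp985 by 2.46 (0.015), Glod5 by 3.58 (0.039) and Rasa4, which overlaps a predicted gene, by 4.30 (0.0073). Of 8 fits without 1 library, Nr0b1 kept its call in 1, Glod5 in 2, and Cald1 and Tdrd12 in 3. In all, 23 genes were called, 9 higher and 14 lower, and 4 of them passed in each line alone. All 23 shared their sign in the 3 lines, against 52.9% of all genes, where simulation with no difference gave 49.6% and 100% of the 23 with the smallest p. The count was 5 without WT replicate 1, 4 without WT replicate 2, 12 without KO1 replicate 1, 39 without KO3 replicate 1 and 42 without KO3 replicate 2, and 4 without the libraries of at least 20% Gm42418. DESeq2 called 139, 107 higher and 32 lower, line as the unit gave 1, and leaving out KO2 gave 9 and leaving out KO3 gave 55 higher and 88 lower.

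Of the genes fixed in advance, several were not past the test at any of the 4 times. Nanog, on chromosome 6, differed by -0.50, -0.74, 0.19 and 0.83 on the log2 scale in 2iL and at 24, 48 and 72 h (adjusted p = 0.91, 0.87, 0.94 and 0.57). The core factors Pou5f1 and Sox2 differed by -0.48 and -0.80 in 2iL (adjusted p = 0.89 and 0.32) and by 0.14 and -0.61 at 72 h (0.94 and 0.45). Fgf5, a marker of the formative state, lay at 10.6 ± 7.76 CPM in KO and 7.69 ± 1.06 in WT at 72 h (0.46, adjusted p = 0.91), and Pou3f1, a POU factor of the same state that overlaps a predicted gene, at 158 ± 109 and 37.9 ± 12.8 CPM at 24 h (2.06, adjusted p = 0.16, but past the test in 7 of 15 other settings, down to 0.00014 without a filter). Dnmt3b, a de novo DNA methyltransferase that overlaps an antisense gene, differed by 0.60, 0.47, -0.03 and -0.76 (adjusted p = 0.68, 0.89, 0.99 and 0.34). The lineage genes T, Eomes, Cdx2, Gata6 and Sox17 had means of at most 8.18 CPM over the KO libraries of a condition (10.8 in a single line, for T) and 2.54 in WT, and none passed.

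The response to withdrawal was measured in WT cells against 2iL, with 2 libraries on each side. At 24 h, formative genes rose and naive genes fell. Dnmt3a rose by 2.77 on the log2 scale (SE 0.38, adjusted p = 1.4e-05), from 23 to 157 CPM, and Dnmt3l, its cofactor, whose gene overlaps Aire, rose by 3.36 (9.1e-06). Nanog fell by 2.55 (SE 0.54, adjusted p = 0.0091), from 283 to 48.3 CPM, and Tfcp2l1 fell by 2.70 (0.011), from 756 to 117 CPM. Of 21 formative genes 6 rose and none fell over all genes, and 12 rose adjusted over the list alone (list adjusted p = 6.07e-21, and 4.44e-08 with an estimated correlation). Of 20 naive genes 2 fell over all genes and 8 adjusted over the list alone (list adjusted p = 1.05e-08, and 0.000574 with an estimated correlation).

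The Nodal antagonist Lefty2 fell by 6.04 in WT at 24 h (SE 0.70, adjusted p = 1.8e-07), from 343 to 5.17 CPM, and Lefty1 by 4.71 (SE 0.75, 0.00015), the 2 of 11 Nodal targets past the test (list adjusted p = 1.05e-08, and 2.68e-05 with an estimated correlation). Halr1, a non-coding RNA of the Hoxa locus on chromosome 6, rose by 5.93 (SE 0.87, adjusted p = 3.4e-05), the protease gene Prss50 by 5.91 (SE 0.66, 8.3e-08), from 1.56 to 93.1 CPM, and Eras, a Ras gene of embryonic stem cells that overlaps Pcsk1n, by 4.91 (0.00032). Myrf, a membrane-bound transcription factor, had 116 counts at 24 h and 2 in 2iL, a ratio of 63.4 (exact 95% counting interval 17.2 to 530), and Bcl11a, a zinc finger gene that overlaps other genes, had 92 and 2, a ratio of 50.3 (13.5 to 422). Plagl1 fell by 4.04 (adjusted p = 0.034), against the rise of its imprinted list (list adjusted p = 0.000674, and 0.0465 with an estimated correlation), of which none of 20 rose over all genes and 4 adjusted over the list alone. S100a13 fell by 3.94 (0.034) and the bicarbonate transporter Slc4a8 by 3.32 (0.045).

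Among other lists in WT at 24 h, FGF/ERK targets rose (list adjusted p = 5.25e-08, and 4.15e-05 with an estimated correlation), with 1 of 18 over all genes, the phosphatase gene Dusp4 on chromosome 8, and 8 adjusted over the list alone. Shared pluripotency genes rose (1.55e-05, and 0.00679 with an estimated correlation), with 3 of 12 over all genes and 5 adjusted over the list alone, led by Utf1, a chromatin factor of stem cells, at 2.47 (SE 0.35, adjusted p = 1.8e-05). The DNA methylation machinery rose (3.69e-06, and 0.000183 with an estimated correlation), as did the cholesterol list (6.91e-06, and 0.0138 with an estimated correlation), the latter with none of 23 by either count. Genes of the integrated stress response fell (0.00581, and 0.0138 with an estimated correlation), with 1 of 20 by either count, Nupr1 at -2.56 (adjusted p = 0.023).

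At 48 h in WT, Ly6a fell by 5.95 (SE 0.99, adjusted p = 0.00013), from 223 to 3.65 CPM, and Calcoco2, a receptor of selective autophagy, by 4.95 (SE 0.66, 2.6e-06). Plagl1 had 444 counts in 2iL and 3 at 48 h, 117-fold lower by the ratio of counts (exact 95% counting interval 39.9 to 571), and Slc52a3, a riboflavin transporter, 194 and 2, a ratio of 76.8 (21.0 to 639). Cass4, a scaffold protein of focal adhesions whose gene overlaps a predicted gene, had 82 counts at 48 h and 1 in 2iL, a ratio of 104 (18.1 to 4140). Of the formative genes 9 of 21 rose over all genes, while 15 rose and 1 fell adjusted over the list alone, and of the naive genes 5 of 20 fell and 10 adjusted over the list alone (list adjusted p = 3.13e-21 and 1.79e-10, and 3.9e-08 and 0.000384 with an estimated correlation).

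At 72 h in WT, 14 of 21 formative genes rose over all genes and 17 adjusted over the list alone (list adjusted p = 8.62e-24, and 1.32e-08 with an estimated correlation). Pou3f1 rose by 5.33 (SE 0.55, adjusted p = 9.5e-09), from 8.11 to 329 CPM. Of 20 naive genes 12 fell over all genes and 15 adjusted over the list alone (list adjusted p = 3.35e-15, and 2.88e-05 with an estimated correlation), among them Tcl1 at -4.28 (SE 0.57, adjusted p = 1.7e-06). Dusp4 rose by 6.24 (SE 0.97, adjusted p = 2.7e-05) and Myrf to 229 counts from 2, a ratio of 148 (exact 95% counting interval 40.6 to 1230). Mael, of the piRNA pathway, went from 1 to 64 counts, a ratio of 82.9 (14.4 to 3320), and Fndc4 from 1 to 60, a ratio of 77.7 (13.4 to 3120). Counts reached 0 for Itpka, a kinase of inositol phosphates, at least 49.4-fold lower, for Lrrc31, which overlaps a predicted gene, at least 43.8-fold, for the delta-catenin gene Ctnnd2, which overlaps non-coding genes, at least 21.9-fold, and for Prdm14, a repressor in naive and germ cells, at least 19.3-fold. Epithelial genes rose, 3 of 20 over all genes and 7 adjusted over the list alone (list adjusted p = 3.93e-05, and 0.000743 with an estimated correlation), led by the adhesion molecule Epcam at 3.77 (SE 0.42, adjusted p = 3.8e-08). Imprinted genes rose as a list (7.42e-10, and 0.000803 with an estimated correlation), 8 of 20 over all genes and 14 adjusted over the list alone.

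In all, 72 genes were called in WT at 24 h, 50 higher and 22 lower, 170 at 48 h, 100 higher and 70 lower, and 500 at 72 h, 257 higher and 243 lower. Of 4 fits without 1 library, Plagl1, S100a13 and Slc4a8 at 24 h, Slc52a3 at 48 h and Ctnnd2 at 72 h kept their calls in 0, and Myrf and Bcl11a at 24 h, Cass4 at 48 h and Mael, Fndc4 and Prdm14 at 72 h in 1. The 24 h count fell to 17 without WT 2iL replicate 1, 17 without replicate 2, and 22 and 28 without WT 24 h replicate 1 or 2. At 48 h it fell to 63 and 60 without WT 2iL replicate 1 or 2, and to 72 and 68 without WT 48 h replicate 1 or 2. At 72 h it was 176 and 182 without WT 2iL replicate 1 or 2, 198 without WT 72 h replicate 2, and 260 without the libraries of at least 20% Gm42418.

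The same response was measured in the KO lines as the equal-weight mean of 3 lines, where the naive and formative programmes also moved. At 24 h, 14 of 21 formative genes rose over all genes and 15 adjusted over the list alone (list adjusted p = 1.09e-22, and 2.08e-08 with an estimated correlation). Pou3f1 rose by 3.27 (SE 0.27, adjusted p = 6e-12), from 17.6 to 186 CPM over the mean of the lines. Of 20 naive genes 11 fell and 1 rose over all genes, and 14 fell and 1 rose adjusted over the list alone (list adjusted p = 3.8e-12, and 0.00011 with an estimated correlation), with Nanog at -2.89 (SE 0.30, adjusted p = 1.7e-09). Cholesterol genes rose, 12 of 23 over all genes, with 17 higher and 1 lower adjusted over the list alone (list adjusted p = 3.73e-16, and 0.00011 with an estimated correlation), led by Msmo1, a sterol oxidase, at 1.13 (SE 0.16, adjusted p = 2.5e-06). Mesendoderm genes fell, 4 of 17 over all genes and 6 adjusted over the list alone (list adjusted p = 0.000129, and 0.00185 with an estimated correlation), led by Sp5 at -3.29 (SE 0.68, adjusted p = 0.0013), a gene that also moved with the run date.

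Wt1, a zinc finger transcription factor of the kidney and gonad, rose by 6.73 in KO at 24 h (SE 0.67, adjusted p = 1.2e-09), from 0.591 CPM (0.293 without KO2 replicate 1) to 34.7 CPM, by 6.12 at 48 h (5.4e-09) and by 5.15 at 72 h (5.4e-07). The 48 h call ended in the earliest run (3.37, adjusted p = 1) and in libraries numbered 1 and 2 (3.36, adjusted p = 1). In WT it rose by 4.53 (0.026), 5.22 (0.0031) and 5.50 (0.00087). Gfra1, a receptor of the neurotrophic factor GDNF that overlaps a predicted gene, rose in KO by 5.24 at 24 h (1e-06) and 5.49 at 48 h (1.6e-07), and Pcdh1, a protocadherin, by 3.94 (1.5e-07) and 4.67 (1.2e-09). Halr1, on chromosome 6, rose by 6.50 at 24 h (1.6e-12) and Stra8, a gene of meiotic entry on chromosome 6, by 3.86 (0.00053). Wdr93 fell by 5.23 at 24 h (7e-05) and 5.92 at 72 h (2.2e-05), the Ets factor gene Spic fell by 4.32 (5.6e-05) and 5.16 (6.7e-06), Prdm14 by 4.11 (0.00076) and 5.49 (1e-04), and the channel gene Trpm1 by 3.75 at 24 h (9.4e-05) and 4.76 at 48 h (1.2e-06). Lefty2 fell by 4.16 at 24 h (6e-12). Calcoco2 fell by 4.00 at 48 h (3.2e-11), and Pla1a, a phospholipase gene, by 4.05 at 48 h (8.5e-07) and 4.97 at 72 h (7.1e-07).

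At 72 h in KO, 17 of 20 naive genes fell over all genes and 19 adjusted over the list alone (list adjusted p = 5.01e-23, and 8.62e-07 with an estimated correlation), and 15 of 21 formative genes rose. Neuroectoderm genes rose, 10 of 16 over all genes, with 11 higher and 1 lower adjusted over the list alone (list adjusted p = 5.44e-09, and 0.0015 with an estimated correlation). Sox1, a marker of neural progenitors, rose by 3.55 (SE 0.50, adjusted p = 7.5e-07), from 2.96 to 32.9 CPM, and Fabp7, a fatty acid binding protein of radial glia, went from 2 to 230 counts, a ratio of 172 (exact 95% counting interval 47.2 to 1430), though its KO mean at 72 h fell from 15.7 to 7.80 CPM without KO1 replicate 2. Spink1, a protease inhibitor, rose by 5.44 (SE 0.55, adjusted p = 2.9e-10), Jakmip2 by 4.91 (4.5e-08) and Vat1l, on chromosome 8 and overlapping another gene, by 4.92 (0.00065). The KO mean of Vat1l at 72 h fell from 12.9 to 5.23 CPM without KO1 replicate 2, and its call ended without KO3 replicate 2 (2.88, adjusted p = 1). Lgals3bp, a secreted galectin ligand, had 197 counts in 2iL and 3 at 72 h, a ratio of 43.8 (14.8 to 214), with a KO mean in 2iL of 12.3 CPM, or 7.55 without KO1 replicate 3. Shared pluripotency genes fell in KO at 72 h, with 6 of 12 lower and 2 higher over all genes, and 8 lower and 2 higher adjusted over the list alone (list adjusted p = 0.000806, and 0.0293 with an estimated correlation).

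In KO, 663 genes were called at 24 h, 334 higher and 329 lower, 1236 at 48 h, 610 higher and 626 lower, and 1860 at 72 h, 873 higher and 987 lower. Each side held 6 or more libraries here and 2 in WT, so the numbers of called genes do not compare the genotypes. At 24 h the count was 415 without KO1 24 h replicate 1, 435 without KO2 2iL replicate 1, 410 and 419 without KO2 24 h replicate 1 or 2, and 420 without KO3 2iL replicate 1. At 48 h it was 796 without KO1 48 h replicate 2, 801 without KO2 2iL replicate 2 and 795 without KO3 2iL replicate 1. With the run date as a term the 24 h count was 1029, and in the earliest run alone the 48 h count was 821.

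The difference between KO and WT responses was tested as an interaction, on the spread within lines only. The response of Dnmt3l was lower in KO than in WT, by a log2 difference of -3.19 at 24 h (SE 0.49, adjusted p = 0.00041), -3.89 at 48 h (9.3e-06) and -3.71 at 72 h (1.4e-05). In KO it lay at 569 CPM in 2iL and at 655, 369 and 184 CPM at the 3 later times, and in WT at 141.5 CPM in 2iL and then at 1450, 1275 and 426 CPM. Prss50 differed by -3.85, -4.74 and -5.55 (adjusted p = 0.0037, 7.7e-05 and 5.6e-06). Upp1 differed by 3.01 at 24 h (SE 0.43, adjusted p = 0.00016), with 625 CPM in 2iL and 425 at 24 h in WT, and 45.0 and 277 CPM in KO.

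Several genes that were low in KO from the start fell in WT cells alone. Ak4 went from 224 to 16.8 CPM in WT and from 4.36 to 18.4 CPM in KO at 48 h, or to 11.3 without KO2 replicate 1 (5.29, SE 0.86, adjusted p = 0.00078), and Ly6a from 223 to 3.65 CPM in WT and from 4.49 to 4.57 CPM in KO (5.41, 0.01). Ppp2r2c, a phosphatase subunit that overlaps an antisense gene, differed by 4.04 at 48 h (0.0025) and the histone deacetylase gene Hdac7, which overlaps Slc48a1, by 4.14 (0.03), a call kept in 6 of 10 other settings. Gjb5, a connexin of trophoblast, differed by 5.44 at 72 h (0.003). Sox21, on chromosome 14 and overlapping a predicted gene, differed by 5.61 at 72 h (SE 1.23, adjusted p = 0.013), with 8.75 CPM in 2iL and 2.56 at 72 h in WT, and 2.00 and 35.6 CPM in KO (21.4 without KO1 replicate 2). Plagl1 differed at 48 and 72 h (adjusted p = 0.013 and 0.0026), Bcl11a at 72 h (0.023) and Adck2, on chromosome 6, at 72 h (0.023), but each rests on a WT group with at most 3 counts or few more. The antigen gene Spn (leukosialin) differed by -4.32 at 48 h (0.04) and -5.09 at 72 h (0.0065), Smpdl3b, a membrane phosphodiesterase, by -3.29 at 48 h (0.031), and Slc27a2, a fatty acid transporter that overlaps a predicted gene, by -2.97 (0.0092). At 72 h Rasa4 and Parp10, which overlap other genes, differed by -5.83 (0.01) and -5.42 (0.046), the call of Parp10 being kept in 6 of 17 fits without 1 library.

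The response of shared pluripotency genes was lower in KO than in WT at 48 h (list adjusted p = 5.6e-06, and 0.0157 with an estimated correlation) and at 72 h (1.58e-05, and 0.0114 with an estimated correlation). At 72 h 4 of 12 were past the test by either count, led by Dppa2, a chromatin factor of early embryos, at -3.11 (adjusted p = 0.001). It went from 24.3 to 69.5 CPM in WT and from 49.6 to 24.0 CPM in KO. Formative genes rose less in KO at 72 h (list adjusted p = 0.00132, and 0.0114 with an estimated correlation), with 2 of 21 lower over all genes, and 2 higher and 6 lower adjusted over the list alone. Those 2 were Dnmt3a at -2.26 (SE 0.45, adjusted p = 0.003) and Foxd3 at -2.80 (0.024). The DNA methylation machinery (0.00743, and 0.0208 with an estimated correlation) and the germline list (0.00743, and 0.0375 with an estimated correlation) were lower too. In all 4 genes differed at 24 h, 1 higher and 3 lower, 28 at 48 h, 12 higher and 16 lower, and 64 at 72 h, 25 higher and 39 lower. The counts were 1 at 24 h without WT 2iL replicate 2, 4 and 2 at 48 h without WT 2iL replicate 1 or 2, 3 and 3 without WT 48 h replicate 1 or 2, and 18, 17 and 15 without KO1 48 h replicate 2, KO2 2iL replicate 2 or KO3 2iL replicate 1. At 72 h they were 18 and 24 without WT 2iL replicate 1 or 2, and 40 and 21 without WT 72 h replicate 1 or 2. DESeq2 called 11, 58 and 159 at the 3 times, line as the unit 0, 10 and 26.

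The position of each library along the WT response was scored as the mean log2 CPM of genes that rose minus that of genes that fell, on genes called in WT libraries of other conditions. Each condition so has its own genes, 45 risen and 42 fallen in 2iL (chosen on WT at 72 h minus 24 h), 257 and 243 at 24 and 48 h (72 h minus 2iL) and 100 and 70 at 72 h (48 h minus 2iL), and the values compare lines within a condition only. In 2iL the mean was -3.24 in WT, -0.10 in KO1, -1.42 in KO2 and -1.49 in KO3 (2, 3, 2 and 2 libraries). At 24 h it was -0.98 in WT and 1.32, 0.29 and 0.11 in the KO lines. At 48 h it was -0.01 in WT and 1.72, 0.57 and 0.82. At 72 h WT stood at 2.14 and the KO lines at 1.16, 1.42 and 1.75. No p is given, since genotype was set by line, with 1 WT line.

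**Figure D4:**
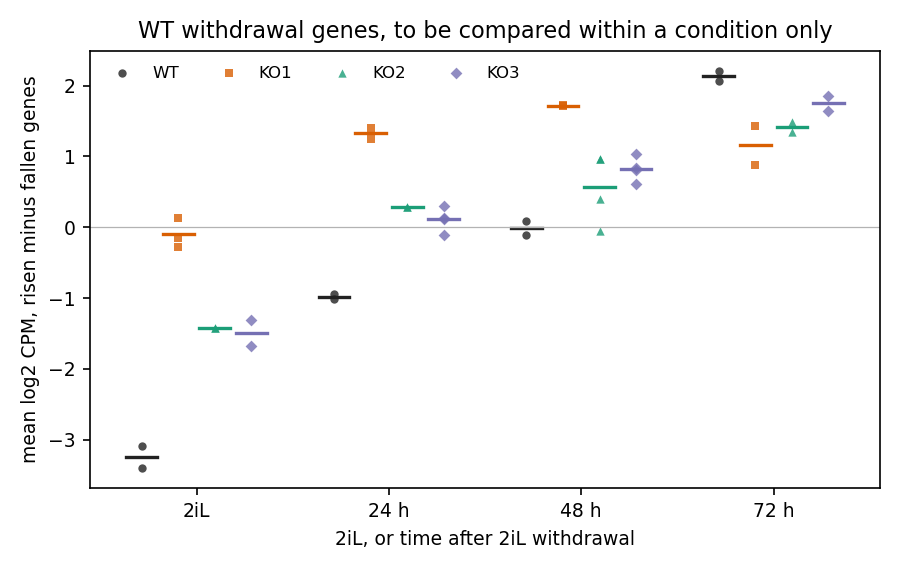
Mean log2 CPM of genes risen minus genes fallen in the WT withdrawal response, in each library by line and condition, with bars at the mean. Each condition has its own gene set but for 24 and 48 h, which share one, so lines compare within a condition only. WT lies at -3.24 in 2iL, below the KO lines, and at 2.14 at 72 h, above them.

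The KO lines also differed from one another. Apart from Esrrb, Zfp42, Pou3f1 and Otx2, the genes named for this were chosen after their values were seen, among those with the smallest p. At 24 h Zfp42, on chromosome 8, lay at 21.1 ± 5.44 CPM in KO1, 84.3 ± 0.444 in KO2 and 119 ± 41.4 in KO3 (SD, n = 2, 2 and 4, adjusted p = 0.014), and Pou3f1 at 317 ± 30.6, 167 ± 15.9 and 73.7 ± 34.2 CPM (0.0046). Otx2, on chromosome 14, lay at 171 ± 23.3, 49.8 ± 3.29 and 70.5 ± 8.07 CPM (0.0016). Slc2a1, a glucose transporter that overlaps predicted genes, held 465 ± 111 CPM in KO1, 184 ± 16.7 in KO2 and least in KO3 (0.00028), and Tpi1, a glycolytic enzyme gene on chromosome 6 that overlaps Spsb2, 269 ± 32.4, 109 ± 49.2 and 52.3 ± 12.1 CPM (9.3e-05).

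In 2iL the Ets factor gene Etv4 lay at 2.26 ± 1.57 CPM in KO1 (n = 3, or 1.36 without replicate 2), 35.9 ± 2.01 in KO2 (n = 2) and 41.5 ± 17.4 in KO3 (n = 2; adjusted p = 1.9e-06), against 65.1 ± 25.0 in WT. Epcam lay at 119 ± 17.4, 20.9 ± 9.91 and 49.5 ± 16.3 CPM (0.00032) and Sycp3, of the meiotic axis, which overlaps Chpt1, at 72.5 ± 48.1 (45.9 without KO1 replicate 2), 5.68 ± 1.52 and 6.77 ± 2.14 (0.001). Bcat1, an aminotransferase gene on chromosome 6, lay at 54.3 ± 2.93 CPM in KO1 and 239 ± 3.38 in KO3, with KO2 between them (0.00028). Esrrb itself differed among the lines in 2iL (0.039). At 48 h Trp53i11, a p53-induced gene, lay at 34.1 ± 7.22 CPM in KO2, 24.6 ± 9.48 in KO3 and highest in KO1 (0.00023). At 72 h Dnmt3l lay at 29.9 ± 14, 168 ± 13 and 352 ± 42.3 CPM (n = 2 each, 1e-04), Tcf15, a bHLH factor of primed cells, at 6.44 ± 3.81 in KO1, 50.8 ± 6.91 in KO2 and highest in KO3 (0.00098), Dppa2 at 4.01 ± 1.56, 26.1 ± 14.9 and 41.8 ± 7.92 (0.00098), and Fgf4 at 5.03 ± 0.636, 28.6 ± 12.7 and 41.5 ± 8.13 (0.0029).

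In all, 33 genes differed among the KO lines in 2iL, 71 at 24 h, 128 at 48 h and 38 at 72 h. In 2iL the count was 12 and 10 without KO2 replicate 1 or 2, 10 and 11 without KO3 replicate 1 or 2, and 9 and 8 without KO1 replicate 1 or 3. At 24 h it was 23 and 10, and at 48 h 16 and 13, without KO1 replicate 1 or 2. At 72 h it was 15 without KO3 replicate 1 and 86 and 4 without KO1 replicate 1 or 2. Without the genes of chromosomes 6, 8 and 14 the counts at 24 and 48 h were 43 and 85.

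Each line was also set against the mean of the other 3, WT included. KO1 differed in 372 genes in 2iL, 176 at 24 h, 316 at 48 h and 323 at 72 h, and WT in 214, 116 and 198, and at 72 h in 116 higher and 37 lower. KO2 differed in 8, 5, 21 and 11 genes and KO3 in 6, 63, 16 and 7. Against WT alone, KO1 differed in 349, 176, 282 and 269 genes, KO2 in 57, 23, 68 and 28, and KO3 in 46, 39, 21 and 14. Whether these numbers differ between lines was not tested.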

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

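The tests of explanations for the 3 patterns weighed here were chosen after the result was seen. In 8 of 35 library measures and 27 of 127 gene levels a library stood apart by its gap to the nearest over the range. Many groups pool 3 KO lines at low CPM, so a chance share of 5% need not hold. KO1 in 2iL, replicate 2, had 21.2% of its counts in Gm42418 (other KO libraries 2.28 to 4.97%) and 12029 genes detected (13290 to 14207), and KO1 at 72 h, replicate 2, had 23.1% in Gm42418 (3.44 to 5.73%). KO3 at 24 h had 3.54% mitochondrial counts in 1 library of replicate 3 (0.518 to 1.23%) and 10844 genes detected in replicate 2, apart both from all KO libraries (13083 to 14167) and from those of its line. That replicate also stood highest in Esrrb, at 146.4 CPM (17.1 to 50.7), Rhox9 (71.7), Igdcc4 (74.7), St8sia1 (2.02) and T (6.06). KO2 at 48 h, replicate 1, the library with the fewest counts, stood highest in Esrrb, at 74.5 CPM (4.53 to 27.2), Tfcp2l1 (124), Eomes (12.4) and Cdx2 (12.4). Other levels that stood apart in 2iL were, in CPM, Parp10 46.9, Klk1 1.23 and 11 for Smarcd3 in KO1 replicate 1, Fgf5 11.6 in replicate 2, Ly6a 11.8, Pou3f1 40.1 and Sox2 287 in replicate 3, Peg10 181 and Cobl 14.3 in KO2, and Msc 5.84 in KO3. At 24 h they were Dgkeos 2.23 and Sox17 2.49 in KO3, and at 48 h H19 2268, Rhox9 81.5 and T 7.24 in KO2 and Csad 51.3 and Gata6 9.84 in KO3. At 72 h they were Adck2 32.5 in KO1, and Rasa4 2.54 and Gata6 16.4 in KO3. The cause of these gaps was not tested.

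Responses differed between genotypes by a test of the interaction in 4, 28 and 64 genes at 24, 48 and 72 h. The log2 differences of those that the rule took as the largest in each direction were at 24 h 3.01 for Upp1, -3.85 for Prss50 and -3.19 for Dnmt3l. At 48 h they were 5.41 for Ly6a, 5.29 for Ak4, 4.14 for Hdac7, 4.04 for Ppp2r2c, -4.74 for Prss50, -4.32 for Spn, -3.89 for Dnmt3l, -3.29 for Smpdl3b and -2.97 for Slc27a2. At 72 h they were 6.69 for Ly6a, 5.61 for Sox21, 5.44 for Gjb5, -5.83 for Rasa4, -5.55 for Prss50, -5.42 for Parp10 and -5.09 for Spn. The fitted values of Plagl1 (6.20 at 48 h and 6.69 at 72 h), Adck2 (8.21 at 72 h) and Bcl11a (-5.66 at 72 h) depend on the prior count, since WT held 3 counts of Plagl1 at 48 h, 0 of Adck2 at 72 h and 2 of Bcl11a in 2iL. As lists, shared pluripotency genes differed with an adjusted p = 0.00242 at 24 h (0.0857 with an estimated correlation), 5.6e-06 at 48 h and 1.58e-05 at 72 h. Nuclear genes of oxidative phosphorylation differed with an adjusted p = 0.00742 at 24 h and 0.0105 at 48 h (0.453 and 0.608 with an estimated correlation), the integrated stress response with 0.0122 and 0.00958 (0.0857 and 0.0285) and cholesterol genes with 0.0328 at 24 h (0.35), each higher in KO. At 72 h the formative list (0.00132), the DNA methylation machinery, germline and imprinted genes (0.00743 each, the last 0.15 with an estimated correlation) and p53 targets (0.043, and 0.0839 with an estimated correlation) were lower, and neuroectoderm genes higher (0.00255, and 0.0981 with an estimated correlation). The KO lines differed from one another in 33, 71, 128 and 38 genes in 2iL and at 24, 48 and 72 h.

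Chromosome 8 as a whole differed between lines of the same genotype, with KO3 above KO1 by 0.53 on the log2 scale, which excludes the Esrrb genotype as the whole cause. A cluster of regulated genes is argued against by the lowest of 3 equal parts of the chromosome, at 0.49, and the run date or depth by 0.56 among libraries of the first run date with at least 1000000 counts. The lowest shift over the 4 conditions was 0.48, near the 0.585 that 3 copies against 2 would give, so a difference in chromosome copy number is a candidate explanation. No DNA was measured here, and which line departs from the usual number was not tested. Small differences on genes of chromosomes 6, 8 and 14 may therefore belong to a line and not to Esrrb, while those such as -3.00 for Zfp42 at 72 h exceed such a shift.

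Connective tissue genes were high in the 9 libraries of the later run dates. Line or time after withdrawal is argued against by the same groups holding both kinds of library, with a median difference of 2.27 in mean log2 CPM of fibroblast genes. Every later library lay above in 5 of 5 such groups, so material that came with the later run dates may be the source. Fibroblasts as the single source are argued against by Alb, of liver, which was counted in 6 of 9 later and 1 of 30 first libraries, and by Reg3b and Spink4, of pancreas and gut, each counted in 5 of 9 and in 0 of 30. Between the run dates 899 genes were called within groups, 562 higher and 337 lower in the later ones, and no biological explanation beyond line and time was tested.

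The KO lines lay ahead of WT on genes of the WT response in 2iL and at 24 and 48 h. Without libraries of later run dates, under 1000000 counts or of at least 20% Gm42418 the lowest gap from WT to the nearest KO line left was 0.99 in 2iL and at 24 h, which argues against run date, depth and Gm42418 there, in 2iL for KO2 and KO3 only, since no KO1 library is left. At 48 h the gap was 0.94, with 1 WT library, 1 of KO3 and none of KO2, the line nearest to WT (0.58 with all libraries), so run date, depth and Gm42418 cannot be told apart there from genotype. The gap exceeded the range of the 3 KO lines in 1 of these 3 conditions, so a loss of Esrrb and differences between any lines cannot be told apart with 1 WT line. At 72 h, all in first-run libraries of at least 1000000 counts, KO lay behind WT. Without those of at least 20% Gm42418 the gap was 0.46, with 1 WT library, so Gm42418 and genotype cannot be told apart. The genes were chosen on the response of WT itself, which can place WT lowest in 2iL and highest at 72 h. This was not tested.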

How the results depend on the processing

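Counts of called genes were recomputed for 17 comparisons under 16 settings, and 85 of 188 such counts stayed within 1.5 times the count in the report while 103 did not. Values below are those that did not, in the order of 2iL, 24, 48 and 72 h, and a count with an exponent is rounded to 2 digits. The settings chosen after seeing the data were libraries 1 and 2 without a number term, the Gm42418 and chromosome exclusions, and the earliest run for the withdrawal responses, the interaction, the differences among the KO lines and the lists. DESeq2 size factors inside edgeR kept 17 of 17 counts within that range. DESeq2 with its own factors called more, at 237, 1.0e+02, 87 and 139 genes for KO against WT, 1.4e+02, 328 and 815 for the WT response, 11, 58 and 159 for the interaction, and 1.6e+02, 227, 256 and 245 among the KO lines. Without an expression filter the counts were 266, 124, 172 and 121 for KO against WT, 260 for the WT response at 48 h, and 1.4e+02, 201, 240 and 141 among the lines. Leaving out KO3 gave 220, 82, 112 and 1.4e+02 for KO against WT, leaving out KO1 gave 46 at 48 h, leaving out KO2 gave 14 at 48 h and 9 at 72 h, and equal weights of the lines gave 214, 116, 198 and 1.5e+02. With the run date as a term the counts were 52, 42 and 62 for KO against WT after withdrawal, 1.5e+02 and 850 for the WT response at 24 and 72 h, 1029 for the KO response at 24 h, 9, 53 and 147 for the interaction, and 117, 205, 254 and 201 among the lines. The earliest run alone gave 60, 2 and 50 for KO against WT after withdrawal, 167 and 902 for the WT response at 24 and 72 h, 821 for the KO response at 48 h, 16 and 193 for the interaction at 24 and 72 h, and 1.4e+02, 295, 295 and 300 among the lines. The replicate number as a block, on libraries numbered 1 and 2, gave 54, 48 and 43 for KO against WT after withdrawal, 135 and 328 for the WT response at 24 and 48 h, 816 for the KO response at 48 h, 8, 64 and 122 for the interaction, and 106, 161 and 163 among the lines in 2iL and at 24 and 72 h. The same libraries without that term gave 58, 67 and 51, then 134, 328 and 753 for the WT response, 7, 63 and 123 for the interaction, and 113, 1.5e+02 and 164 among the lines. Libraries of at least 1000000 counts gave 61 among the lines at 72 h. Without libraries of at least 20% Gm42418 the counts were 4 for KO against WT, 260 for the WT response and 33 for the interaction at 72 h, and 53, 129 and 4 among the lines in 2iL and at 24 and 72 h. For these settings the cause was not tested. Fewer genes were left without chromosomes 6, 8 and 14, which gave 43 and 85 among the lines at 24 and 48 h. Line as the unit has fewer samples, while the main fits count libraries of 1 line as independent. It gave 20, 1, 2 and 1 for KO against WT and 0, 10 and 26 for the interaction. A test against a 2-fold change asks for more by construction and gave 10, 2, 6 and 1.

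Each library was also left out in turn, with a lone library of a group assumed to vary like the other groups, and 55 of 184 counts moved by more than 1.5 times, downwards except for KO against WT at 72 h without either KO3 library and for the KO lines at 72 h without KO1 replicate 1. The lowest and highest counts were 6 and 133, 1 and 29, 1 and 34, and 4 and 42 for KO against WT, 17 and 28, 60 and 72, and 176 and 406 for the WT response, 410 and 717, 795 and 1303, and 1339 and 1894 for the KO response, 1 and 4, 2 and 31, and 18 and 74 for the interaction, and 8 and 41, 10 and 99, 13 and 133, and 4 and 86 among the KO lines. The lowest for KO against WT came each time without a WT library, which leaves 1 library in that group.

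No named gene and no list changed direction in a called result. Called genes kept their call in 1600 of 1789 settings and 1355 of 1686 fits without 1 library, and called lists in 468 of 593. Of 925 values of named genes not called, 35 passed the threshold under another setting. The replicate numbers do not pair the libraries, since over 48 pairs of groups of the same condition or line the correlation of libraries with the same number ran from -0.168 to 0.117 with a median of 0. Depth and spread limit what is seen: of simulated 8-fold changes at 72 h, edgeR recovered 53% for KO against WT and 37.9% for the interaction.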

Other observations

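Of 29 lists 25 were called in at least 1 of 13 contrasts, and 8 of them lost the call in every contrast with an estimated correlation. Among those 8, genes of the 2-cell-like state were higher in KO at 24 and 48 h (adjusted p = 0.00443 and 0.0166, and 0.117 and 0.195 with an estimated correlation), with 6 of 6 tested members higher and none past the test by edgeR. BMP targets were higher in KO at 72 h (adjusted p = 0.00713, and 0.0605 with an estimated correlation), 8 of 9. Partners and targets of the oestrogen-related receptors, a list that leaves out Esrrb, were lower in KO at 48 h (adjusted p = 0.0166, and 0.159 with an estimated correlation), 6 of 6, 3 of them adjusted over the list alone, and fell in KO at 48 h (0.0281, and 0.136 with an estimated correlation) and 72 h of withdrawal (0.00779, and 0.0699). Wnt targets fell in KO at 24 h of withdrawal (adjusted p = 0.00264, and 0.069 with an estimated correlation), 3 of 15 lower and 1 higher over all genes. Mesenchymal genes were higher in KO at 24 h (adjusted p = 0.0485, and 0.425 with an estimated correlation), 12 of 15, a call that ended in the earliest run alone (adjusted p = 0.362) and without KO3 (0.624), the 1 line with later libraries at 24 h. Proliferation genes, with none of 30 past the test over all genes in WT and 1 in KO, rose at 24 h in WT (0.0255, and 0.19 with an estimated correlation) and KO (0.00489, and 0.0892 with an estimated correlation). The fibroblast list was higher in KO in 2iL (0.00727) and at 24 h (0.0108), with 0.421 and 0.425 with an estimated correlation, rose at 48 h of withdrawal in WT (0.00903, and 0.438) and KO (0.0208, and 0.549), and followed the run date. Nuclear genes of oxidative phosphorylation were lower in KO at 24 h (0.0131, and 0.425) and 72 h (0.00587, and 0.434) too, and fell in WT at 24, 48 and 72 h (0.0182, 2.65e-05 and 0.0458, and 0.595, 0.193 and 0.604). The 4 lists called in no contrast were the TCA cycle (smallest adjusted p = 0.0533), the mitochondrial genome (0.0919), glycolysis (0.0942) and blood and endothelium (0.225).

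The KO response to withdrawal was set against other splits of the same KO libraries within lines, a test chosen before its result was seen. Of 33 splits at each time, the real one included, drawn from 900, 2250 and 360 possible, 1 gave as many genes, the real one. Fitted to the KO libraries alone, the real split called 544, 1149 and 1798 genes at 24, 48 and 72 h. The highest other split called 408, 2 and 468, so no other split drawn called as many. A share of 1 in 33 is the smallest that 33 splits can give, so chance is not excluded, and the splits not drawn were not tested. Other splits mix libraries in 2iL with later ones within a line, which widens their spread and lowers their calls. The highest other count depends on the draw, since an earlier draw from another seed gave other values, each below the real one. The median of the other splits was 0 genes by edgeR at each time. At an unadjusted p under 0.05 the real split held 2106, 2883 and 3431 genes and the highest other 2362, 1968 and 2372, so at 24 h 1 of the 32 other splits held more than the real one.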
